A study of Mus musculus with 2 samples.

How the data were processed

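The series holds 1 pooled sample of lung T cells, split at GEO into 2 libraries, 1 of gene expression and 1 of hashtag antibodies, made with the 10x Chromium 5' chemistry per the labels' protocols. Cells carried the pan-leukocyte marker CD45, and the antibody injected before the lungs were taken told vascular from extravascular T cells, per the labels' protocols. The 4 conditions given in the authors' hashtag list were CD69-positive and CD69-negative cells of day 29 and of day 46. Each had 1 hashtag, and the number of mice pooled under a hashtag is not given in the sources used here. The matrix holds 6 hashtags, of which 2 are not named in the authors' list and were not used here.

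The deposited matrix holds raw UMI counts per gene and barcode from Cell Ranger 5.0.0, per the file headers, on the build mm10, per the submitters' processing notes. It has 13905 barcodes and 32285 genes. The authors' deposited cell table lists 5765 of these barcodes, each with 1 hashtag call. Its totals equalled the sums of the matrix counts in all 5765 cells. The table came from Seurat, whose version 4.1.1 is named in the submitters' processing notes. The filter behind it is not given in the sources used here. Listed cells had 508 to 4971 genes, 666 to 19987 UMIs and at most 4.00% mitochondrial UMIs. The remaining 8140 barcodes were left out. The deposited cell table also gives a hashtag margin, a score that the authors obtained by subtracting the next highest from the highest hashtag value of a cell after centred log-ratio scaling, as its column name and values show. A deposited table of normalized expression holds natural log values of 1 plus the SCTransform-corrected count, made by the authors with Seurat per the submitters' processing notes. Its 13922 rows carry no gene names. They were matched to genes with a UMI in 5 or more listed cells by order, and for 5 of 5 studied genes checked the expected row correlated best with the counts (r from 0.871 to 0.970 across cells, next best at most 0.427). The table of log-ratio values per hashtag was not used here.

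A cell with 2 or more hashtags was not listed by the authors. Doublets within 1 hashtag stay in, since no doublet caller was run. No further filter on cells was applied. A UMI of Cd3e was seen in 95.6% and of Cd4 in 67.2% of listed cells. Cd8a had 0 UMIs in all barcodes of the matrix, so CD8 T cells were judged by other genes. Total UMIs were 36350677 over the 4 hashtags, from 7085532 to 11840229 each, so that a gene with no UMI could lie as high as 0.253 to 0.423 CPM (3 counts of the total). Median genes per cell were 2735.5 and 2264 in CD69-positive and 1639 and 1678 in CD69-negative cells on day 29 and day 46. The median hashtag margin was 1.82 and 3.48 in CD69-positive and 2.78 and 3.56 in CD69-negative cells. Genes that share a symbol, 38 symbols in all, were kept apart by their identifiers. The studied genes were Icos (ENSMUSG00000026009), Tnfrsf4 (ENSMUSG00000029075), Tnfrsf8 (ENSMUSG00000028602), Icosl (ENSMUSG00000000732), Tnfsf4 (ENSMUSG00000026700) and Tnfsf8 (ENSMUSG00000028362). Gene positions came from the RefSeq table of GRCm38.p6, matched by symbol.

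Raw counts were summed per hashtag and scaled to CPM. With 1 hashtag per condition, differences between conditions were described by the log2 fold with 10 CPM added to both values, and exact Poisson 95% intervals. Genes entered a comparison with 50 or more UMIs in the populations compared and 50 or more CPM in one of them, which left 3294 genes for CD69 on day 29 and 3208 on day 46, and 3098 and 3094 for the day in CD69-positive and CD69-negative cells. Genes named in the text were the 12 highest and 12 lowest folds of a comparison, the 6 studied genes and up to 4 genes per list with the largest fold and 50 or more UMIs. Genes of the both-days count and of its figure, and genes raised because of single barcodes, cell class or sex, were named after their values were seen. Ribosomal, mitochondrial, T cell receptor, immunoglobulin, hemoglobin, Xist, Y-linked and unnamed genes were kept out of that ranking; of these, 7 of 153 and 6 of 149 differed at least 2-fold by CD69 on day 29 and day 46, and 2 of 150 and 0 of 144 by day.

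Gene lists covered Th2, Th1, Th17, regulatory, follicular helper, naive or central memory, tissue-resident memory and cycling T cells, the studied genes, other costimulatory receptors, survival, cytokines, chemokines and their receptors (with S1pr1, S1pr4 and Gpr183), interferon, NF-kB, dissociation, cytotoxic granules, glycolysis and lipid handling. A list was described by its median log2 fold, the percentile of that median among 10000 random lists drawn from the 100 genes nearest in expression to each member, and the number of members at least 1.5-fold higher or lower. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs, with exact (Clopper-Pearson) 95% intervals.

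Cells were clustered on the natural log of 1 plus counts per 10000, with 2000 variable genes that left out receptor segments and the 6 studied genes, 30 components, 15 neighbours and Leiden resolution 0.8 with seed 0. A cluster took a class name when 3 or more markers of that class were among its 10 leading genes and no other cell type's list had as many. The names in use were Th2, Th1, Th17, naive or central memory and cycling. The lists of T cells, CD4 T cells and tissue-resident memory cells gave no names. A cluster of 487 cells with Nr4a1, Nr4a3 and Ramp3 of the tissue-resident memory list among its leading genes thus kept none. The markers, lists, thresholds, named-gene rule and tests of the comparisons were fixed before the data were examined, while some tests of explanations were chosen later. The wording of the naming rule, the choice of Th2-like cells against other classes and the requirement that a gene pass the filter on both days were settled after the data had been seen. Of 13 clusters, 7 kept no class name. Counts of classes with 20 or more cells per hashtag were summed per class and hashtag and tested with edgeR's quasi-likelihood method after TMM normalization with the hashtag as a block, over 7769 genes for Th1-like and 7961 for Th17-like cells. The 10 tests on the studied genes were adjusted together by Benjamini-Hochberg. Cells of the naive or central memory class were too few in CD69-positive hashtags (17 and 16) for a test in the main clustering, and were tested only with the stricter cell filter (22 and 26). Class shares were not tested between conditions, because genes that define the clusters differ between the conditions.

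Alternatives fixed in advance were TMM scaling, 200 or more UMIs, 1 and 50 CPM added, the upper 75% of cells by hashtag margin, cells with a Cd4 UMI and no Cd8 UMI, thinned cells, the authors' normalized values, cells under 5% mitochondrial UMIs with 1000 or more UMIs, DESeq2, no hashtag block and each hashtag left out. Alternatives chosen after seeing the data were a fit of the 4 sums with CD69 and day as terms, leaving out cycling cells, only cells with an Xist UMI and no Y-linked UMI, leaving out 1 barcode, genes past the filter on either day, and other clusterings and a minimum of 50 cells for the class tests. Steps were tested on simulated counts. For the fits, these were drawn with the same dispersion for every gene and no hashtag effect, and classes were given rather than clustered. In the class test over 7726 genes, 46.7%, 85.9% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 13 false calls among 160. That share of false calls lay above the threshold of 0.05. In the fit with CD69 and day as terms over 11225 genes the shares were 47.0%, 84.8% and 100%, with 2 false calls among 155. Intervals covered the true ratio in 95.0% to 97.8% of draws, and thinning erred by at most 0.0599 percentage points. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.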

Results

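T cells from the lungs of mice with an allergic response to house dust mite (HDM) extract were profiled by droplet single-cell RNA sequencing from the 5' end of transcripts, together with hashtag antibodies that mark which sample a cell came from. Mice received 20 µg HDM with 2 mg of the adjuvant alum into the peritoneum, and later 10 µg HDM into the nose on days 10 to 13, on days 27 to 30 and on days 44 and 45. An antibody to CD90.2 given into the blood 10 minutes before the lungs were taken stained T cells inside vessels, so that unstained cells counted as extravascular. The title of the series concerns the persistence of CD4 tissue-resident memory T cells and the ligands of ICOS, OX40 and CD30. The 4 hashtags named by the authors mark CD69-positive and CD69-negative cells of day 29, which lies within the challenge of days 27 to 30, and of day 46, the day after the last challenge. CD69 is a surface protein that holds T cells in tissue by taking the egress receptor S1PR1 off the cell surface. The CD69-positive populations held 1078 cells on day 29 and 1601 on day 46, with 10230234 and 11840229 unique molecular identifiers (UMIs). The CD69-negative populations held 1579 and 1507 cells, with 7194682 and 7085532 UMIs. Median UMIs per cell were 8738.5 and 6560 in CD69-positive cells and 3961 and 4079 in CD69-negative cells, on day 29 and day 46. Each condition had 1 hashtag, and the number of mice behind a hashtag is not given in the sources used here. A difference between 2 conditions therefore has no replicate check and was described without a test, and all intervals cover counting error only. A fit of all 4 sums with CD69 and day as terms, in which the other day stands for a replicate, was added only after the data had been seen. Levels are UMIs of the summed cells scaled to a common total (CPM) with exact Poisson 95% intervals, and log2 folds were taken after adding 10 CPM to both values. Gene positions are those of the mouse assembly GRCm38.p6, of the build mm10.

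The comparison of CD69-positive with CD69-negative cells asks how cells that carry the retention marker differ from sorted cells that lack it. The submitters describe the sequenced T cells as extravascular, which was not checked here. CD69-positive cells carried more mRNA of the type 2 cytokines that drive eosinophilia and mucus production. Il13 (chromosome 11, 53631323 to 53634702) stood at 2504 CPM (2473 to 2535) in CD69-positive and 449.5 CPM (434 to 465) in CD69-negative cells of day 29, a log2 fold of 2.45, and at 1350 and 488 CPM on day 46, a log2 fold of 1.45. Il5 (chromosome 11, 53720794 to 53725103), the eosinophil growth factor, had log2 folds of 2.84 on day 29 and 1.30 on day 46, from 801 against 103 CPM and 482 against 189 CPM. Ccr8, a chemokine receptor of type 2 helper (Th2) cells, was at 345 against 123 CPM and 449 against 186 CPM. Of the 16 Th2 genes fixed in advance, 9 were at least 1.5-fold higher and 0 lower on day 29, and 8 were higher and 1 lower on day 46. The 5 that were higher on both days were Il5, Il13, Ccr8, Igfbp7 and Pparg, the last a lipid-sensing transcription factor. The median log2 fold of the list was 0.88 and 0.67, at percentile 100 of 10000 random lists matched on expression on either day. After each cell was thinned to 2000 UMIs, which left out 8, 106, 45 and 98 cells of the CD69-positive and CD69-negative populations of day 29 and then of day 46, an Il13 UMI was seen in 51.6% and 13.4% of cells on day 29 and in 46.6% and 17.6% on day 46. The unthinned shares were 64.3% and 17.7%, then 59.8% and 23.0%. Background was read from a cluster of 46 cells with natural killer receptor genes among the CD69-negative cells of day 29, where 1 thinned cell (2.17%, exact 95% interval 0.0550% to 11.5%) held Il13 at a median of 4880 UMIs. The shares also reflect the sort on CD69 and the deeper sampling of CD69-positive cells.

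Genes for leaving tissue and for circulating through lymph nodes lay on the other side. Klf2 (chromosome 8, 72319062 to 72321654), the transcription factor that switches on S1pr1, was at 51.03 CPM (46.7 to 55.6) in CD69-positive and 845 CPM (824 to 866) in CD69-negative cells of day 29, with log2 folds of -3.81 on day 29 and -3.35 on day 46. S1pr1 (chromosome 3, 115710433 to 115715055), the receptor that guides cells out of tissue, had log2 folds of -3.02 and -2.83, from 12.8 against 175 CPM and 8.78 against 123 CPM. Klf3 followed with -2.68 and -2.73 and Gramd3 with -2.38 and -2.75. All 9 measured genes of the naive or central memory list were at least 1.5-fold lower in CD69-positive cells on day 29, and all 7 on day 46. They include Tcf7 (-1.80 and -1.50) and Lef1 (-1.32 and -1.10), transcription factors of undifferentiated T cells, and Ccr7 (-1.33 and -0.97), the lymph node homing receptor. The list's median was -1.32 and -1.33, at percentile 0 on both days. The list of chemokines and chemokine receptors, which also held the lipid receptors S1pr1, S1pr4 and Gpr183, split by gene. Ccr6, Ccr7, Cxcr3, Cxcr4, S1pr1, S1pr4, Gpr183 and the chemokine Ccl5 were at least 1.5-fold lower in CD69-positive cells on both days, while Ccr8, Cxcr6, Ccl1 and Xcl1 were higher, among 17 measured genes with list medians of -0.77 and -0.59. With thinned cells the medians were -0.35 and -0.54. Cxcr6, a receptor of lung-resident T cells, was at 759.6 against 445.5 CPM and 716 against 414 CPM.

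Genes of cytotoxic granules were mostly lower in CD69-positive cells on both days, genes of type 1 helper (Th1) cells were lower throughout on day 29 and in part on day 46, and part of the interferon response was lower. All 8 Th1 genes were at least 1.5-fold lower on day 29 and 4 of 8 on day 46, with medians of -1.19 and -0.73 at percentile 0. Cxcr3, the receptor for interferon-induced chemokines, had log2 folds of -1.57 and -1.32, and Ly6c2 had -2.02 and -1.54. In the cytotoxic list 5 of 6 measured genes were lower on each day, with medians of -1.16 and -0.72. The granule protease Gzma had -1.30 and -1.64, and Fasl, the ligand that triggers death through Fas, had -1.34 and -0.77. Marker genes of natural killer cells, which share some of these genes, summed to 55.0 and 189 CPM in CD69-positive and CD69-negative cells of day 29, and to 34.3 and 113 CPM on day 46. Markers of CD8 T cells, which share Ccl5 and Nkg7 with the Th1 list, summed to 675 and 1726 CPM on day 29 and to 675 and 1423 CPM on day 46. In the interferon list 6 of 11 genes were at least 1.5-fold lower on day 29 and 4 of 10 on day 46, with medians of -0.89 and -0.40, and with Isg15, Ifit1, Irf7 and Gbp2 lower on both days, and Irf7, a transcription factor of that response, at -1.33 and -0.97. The survival list had medians of -0.21 and -0.44. In it Bcl2, Mcl1, which both block cell death, and Il7r, the receptor for the survival cytokine IL-7, were lower on both days, with Bcl2 at -1.58 and -0.98 and Il7r at -1.43 and -0.77, while Bcl2a1d and Birc5 were higher.

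Genes of dividing cells were higher in CD69-positive cells. All 9 cycling genes were at least 1.5-fold higher on both days, with medians of 2.25 and 1.70. Mki67, a marker of dividing cells, was at 209 against 46.2 CPM on day 29 and at 125 against 31.5 CPM on day 46, and Rrm2, which makes DNA building blocks, had log2 folds of 2.53 and 1.92. Thinned cells held an Mki67 UMI in 17.4% and 4.14% of CD69-positive and CD69-negative cells of day 29 and in 10.4% and 3.55% on day 46 (unthinned 34.1%, 7.41%, 20.4% and 6.11%), against 1 of 46 cells (2.17%, exact 95% interval 0.0550% to 11.5%) in the natural killer receptor cluster at a median of 4880 UMIs. All of these thinned shares but that of CD69-positive cells of day 29 lie within that interval, which is wide as it rests on 46 cells, so it does not set them apart from background. A cluster of cycling cells, with a Top2a UMI in 93.6% of its cells, held 163 and 122 CD69-positive and 22 and 20 CD69-negative cells on day 29 and day 46. Without the cluster of cycling cells the list medians were 1.14 and 0.82, the histone gene Hist1h2ae went to -0.03 and -0.09, and Hist1h1b went to -0.39 on day 46. Glycolysis genes had medians of 0.56 and 0.33, with 5 of 11 at least 1.5-fold higher on day 29 and 0 of 11 on day 46. Of the lipid list, Fabp5, a fatty acid carrier, was at 225 against 73.1 CPM and 189 against 94.7 CPM, and Plin2, which coats lipid droplets, had log2 folds of 0.95 and 1.04. The list medians were 0.61 and 0.50 over the 6 measured genes, and 0.25 and 0.03 over all 9 listed. Inhibitory receptor genes Lag3 (1.40 and 1.63), Havcr2 (0.77 and 1.35), Pdcd1 (0.60 and 1.09) and Klrg1 (0.88 and 0.81) were higher, and Btla and Slamf6 were lower, within a costimulatory list of 18 genes whose medians were 0.05 and 0.07. Follicular helper genes had medians of 0.60 and 0.50, with Il21, Pdcd1 and Tox2 higher on both days. The cytokine list had medians of 0.93 and 0.35. Il17a, the cytokine of Th17 cells, was at 388 against 273 CPM and 354 against 172 CPM, although the Th17 list had medians of -0.31 and -0.35.

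The sorted marker itself differed little as mRNA. Cd69 (chromosome 6, 129267324 to 129275375) was at 429 CPM (416 to 441.5) in CD69-positive and 476 CPM (459.8 to 492) in CD69-negative cells of day 29, and at 526 and 455 CPM on day 46, log2 folds of -0.15 and 0.20. The tissue-resident memory list, which holds Cd69, had medians of 0.11 on both days at percentiles 79.95 and 90.5. In it Cxcr6 was at least 1.5-fold higher on both days and Hopx, Ramp3 and Vps37b were lower, and the remaining 14 of 18 genes were not that far apart in 1 direction on both days. The list of dissociation and immediate early genes, which handling of tissue can induce, had medians of -0.44 and -0.48, with the heat shock gene Hspa1a at -2.43 and -1.24. The NF-kB list had medians of 0.04 and -0.28, and the regulatory T cell list 0.34 and 0.04.

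Of 3127 genes past the count filter on both days, 37 were at least 2-fold higher and 44 at least 2-fold lower in CD69-positive cells on both days, and 0 were 2-fold apart in opposite directions. The log2 folds of day 29 and day 46 correlated across genes with r = 0.870, genes not being independent replicates. The receptor Il1r2, a decoy for IL-1, was among the higher genes with 1.87 and 1.99, and Penk, the precursor of enkephalins, with 1.27 and 2.69. The membrane protein gene Ms4a4b was among the lower genes with -1.78 and -1.72, and the signalling inhibitor Socs3 with -1.67 and -1.85. The low Retnla (-3.65) and Sftpc (-2.51) folds of day 29 rested on 1 barcode of the CD69-negative population, which held 1217 of 1240 Retnla and 473 of 500 Sftpc UMIs, and without it they were 0.14 and 0.03. With 50 CPM added in place of 10 CPM, the numbers of genes were 13 and 23.

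**Figure D1:**
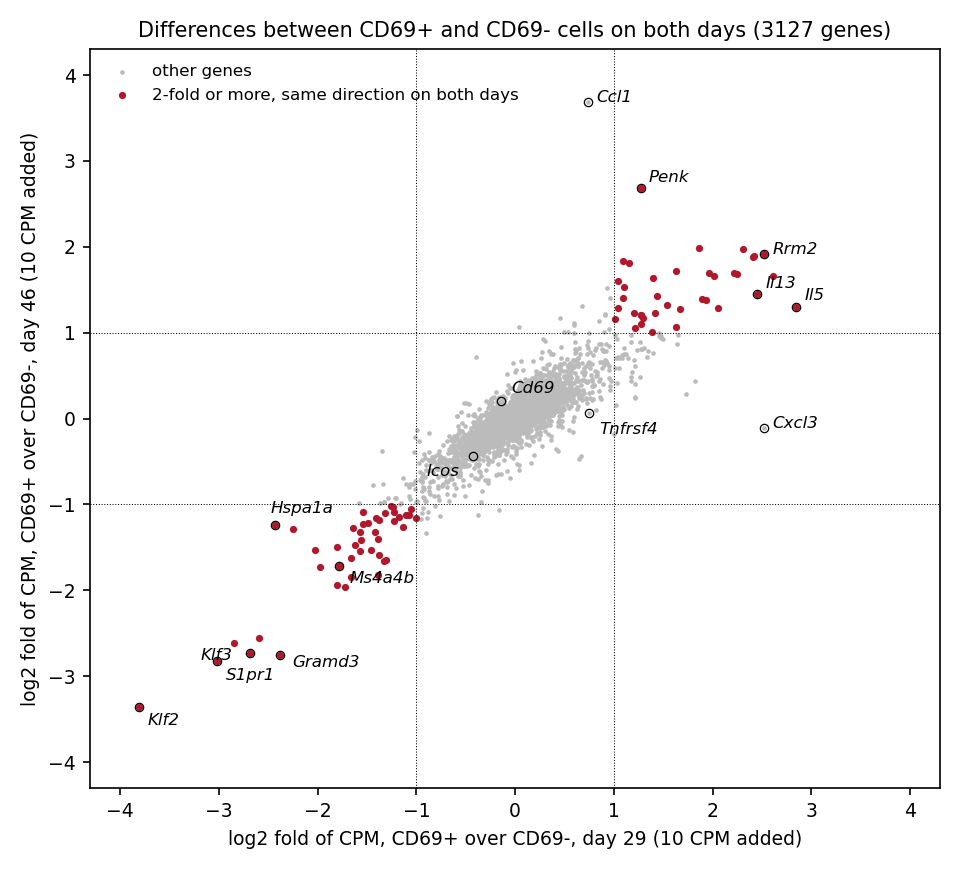
Each point is 1 of 3127 genes, with its log2 fold of CPM in CD69-positive over CD69-negative cells (10 CPM added) on day 29 on the horizontal axis and on day 46 on the vertical axis. Red points are at least 2-fold apart in the same direction on both days, 37 higher and 44 lower, with Klf2 at -3.81 and -3.35, Il5 at 2.84 and 1.30, and Cd69 near 0 at -0.15 and 0.20.

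**Figure D2:**
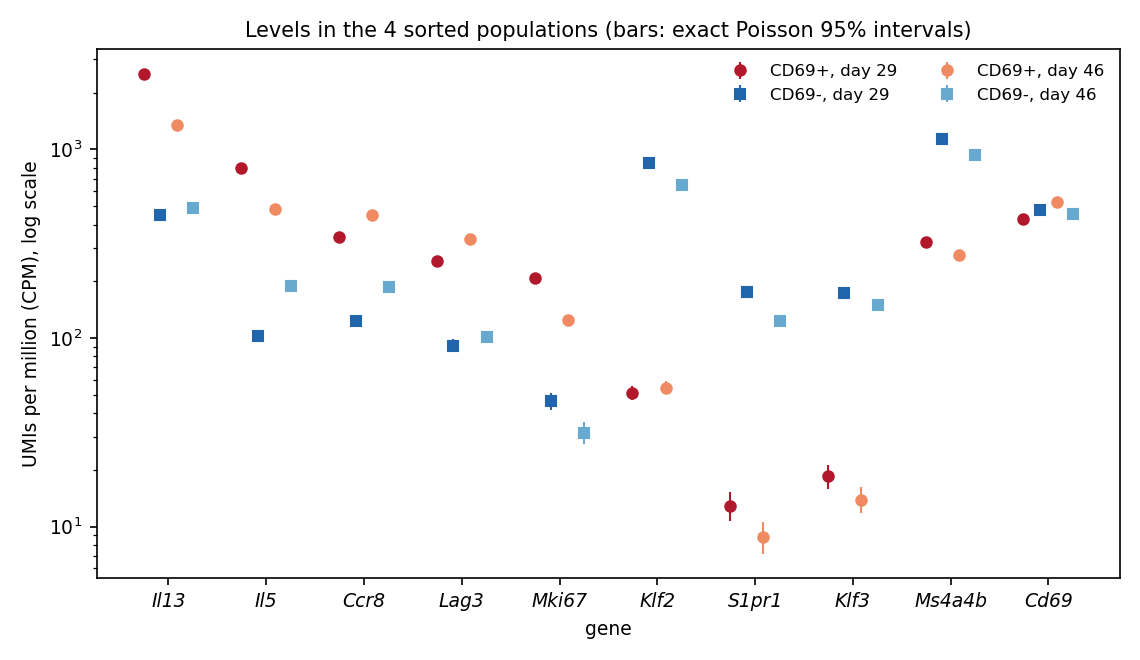
Points give the CPM of 10 genes, on a log axis, in the CD69-positive (circles) and CD69-negative (squares) populations of day 29 and day 46, with bars for exact Poisson 95% intervals that cover counting error only. Il13 stands at 2504, 449.5, 1350 and 488 CPM in CD69-positive and CD69-negative cells of day 29 and then of day 46, and Klf2 at 51.03, 845, 54.5 and 649 CPM.

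The comparison of day 46 with day 29 asks how the same sorted population differs between a late day of one challenge and the day after the next. Few genes stood 2-fold apart. In CD69-positive cells Calca, the precursor of the neuropeptide CGRP, was at 99.6 CPM on day 29 and 415 CPM on day 46, a log2 fold of 1.96 (0.84 in CD69-negative cells). The heat shock genes Hspa1a and Hspa1b had 1.66 and 1.61, the mRNA decay factor Zfp36l2 had 1.27, and Tsc22d3, a glucocorticoid-induced gene, had 1.15. The neutrophil chemokine Cxcl3 was at 496 and 112 CPM, a log2 fold of -2.06, and the T cell growth factor Il2 had -1.60, with 284 of its 689 UMIs on day 29 in 1 barcode. The Il2 fold was -0.56 in cells with Xist and no Y-linked UMI, and turned to 0.81 with the upper 75% of cells by hashtag margin. In CD69-negative cells the epidermal growth factor family member Areg was at 683 and 1480 CPM, a log2 fold of 1.11, the natural killer receptor gene Klrd1 had -1.13 and the chemokine Ccl1 had -2.22, with 387 of its 872 UMIs on day 29 in 1 barcode. Retnla (-3.64) and Sftpc (-2.36) in CD69-negative cells went to 0.15 and 0.17 without the same single barcode. In CD69-positive cells 7 genes were at least 2-fold higher and 2 lower on day 46, and in CD69-negative cells 1 was higher and 4 were lower, which includes 2 genes of left-out classes (a T cell receptor segment and an unnamed model) among the 7. With the upper 75% of cells by hashtag margin, which left 127 CD69-positive cells of day 29, the numbers in CD69-positive cells were 12 and 24.

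By gene list, cycling genes were lower on day 46 in CD69-positive cells, with 7 of 9 at least 1.5-fold lower and a median log2 fold of -0.72, and a median of -0.22 in CD69-negative cells. The latter was 0.02 after thinning and -0.55 in cells with Xist and no Y-linked UMI, so that its direction depends on the setting. Interferon genes had medians of -0.23 and -0.35 in CD69-positive and CD69-negative cells, and cytotoxic genes -0.18 and -0.34. The Th1 list had 0.10 and -0.29, the naive or central memory list -0.10 and -0.38, the Th17 list -0.15 and -0.09 and the cytokine list -0.21 and 0.06. The Th2 list had 0.04 and 0.10, the tissue-resident memory list -0.01 and 0.07, and the regulatory T cell list 0.10 and 0.28. For the remaining lists the medians were 0.14 and 0.13 (follicular helper), 0.05 and 0.01 (other costimulatory), -0.07 and 0.08 (survival), -0.08 and -0.13 (chemokine), -0.01 and 0.16 (NF-kB), 0.12 and 0.14 (dissociation), -0.11 and 0.19 (glycolysis) and -0.19 and 0.05 (lipid). Besides medians within 0.1 of 0, several turned with the setting. In CD69-positive cells the Th1 and regulatory medians were -0.21 and -0.09 with the stricter hashtag margin, the Th17 median was 0.03 after thinning and the cytotoxic median 0.09 with 200 or more UMIs. In CD69-negative cells the cytotoxic median was 0.01 in cells with a Cd4 and no Cd8 UMI, and the follicular helper median -0.03 in cells with Xist and no Y-linked UMI. The day folds of CD69-positive and CD69-negative cells correlated across 2817 genes with r = -0.018, genes not being independent replicates. The spread of log2 folds across genes was 0.19 (SD) in both day comparisons, against 0.51 and 0.41 between CD69 populations on day 29 and day 46. The days also differed in the sex of cells: a UMI of a Y-linked gene was seen in 148 of 1078 (13.7%) and 231 of 1579 (14.6%) CD69-positive and CD69-negative cells of day 29, and in 5 of 1601 (0.312%) and 8 of 1507 (0.531%) of day 46.

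UMIs of the receptors whose ligands the series title names were counted in both sorted populations. Tnfrsf4 (chromosome 4, 156013595 to 156016613), which encodes OX40, was at 775 CPM (758 to 792) in CD69-positive and 458 CPM (442.5 to 474) in CD69-negative cells of day 29, a log2 fold of 0.75, and at 642 and 616 CPM on day 46, a log2 fold of 0.06. Icos (chromosome 1, 60960773 to 61000322) was lower in CD69-positive cells on both days, with 394 against 534 CPM and 421 against 571 CPM, a log2 fold of -0.43 each time. Tnfrsf8 (chromosome 4, 145267132 to 145315164), which encodes CD30, was rare, with 177 and 34 UMIs in CD69-positive and CD69-negative cells of day 29 (17.3 and 4.73 CPM) and 209 and 68 UMIs on day 46 (17.6 and 9.60 CPM), and its level in CD69-negative cells was not told apart from free RNA. Of the ligands, Tnfsf8 for CD30 (chromosome 4, 63831202 to 63861508) was at 412 against 232 CPM and 413 against 278 CPM. Icosl (chromosome 10, 78069368 to 78079525) lay between 12.8 and 18.2 CPM in the 4 populations. Tnfsf4 for OX40 (chromosome 1, 161395438 to 161418206) had 16, 1, 7 and 3 UMIs in CD69-positive and CD69-negative cells of day 29 and then of day 46, near the limit of detection. The list of these genes had medians of 0.75 on day 29 and 0.06 on day 46 between CD69 populations, and of 0.00 and 0.25 between days in CD69-positive and CD69-negative cells. After thinning, 55.4% and 36.3% of CD69-positive and CD69-negative cells of day 29 and 47.7% and 43.1% of day 46 held a Tnfrsf4 UMI (unthinned 77.5%, 45.6%, 70.1% and 53.8%), against 1 of 46 cells (2.17%, exact 95% interval 0.0550% to 11.5%) in the natural killer receptor cluster.

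The comparison of T cell classes within hashtags asks which kinds of lung T cells carry these receptors. Classes were taken from clusters formed without the studied genes and named by markers fixed in advance. Clusters without a class name were left out of this comparison. Among them a cluster led by Il21, described under other observations, carried more Tnfrsf4 than the classes compared here in each hashtag. Th2-like cells joined a cluster led by Il10, Areg, Calca and Il13 and a cluster led by Il1r2 and Pcsk1, Th1-like cells were led by Nkg7, Ifng and Cxcr3, and Th17-like cells by Ccr6, Tmem176b and Aqp3, with the interferon gene Isg15 also among the leading genes. In the CD69-negative population of day 29 most Th2-like cells (118 of 182) came from the cluster led by Il1r2, elsewhere from the other. Tnfrsf4 was at 865 to 1249 CPM over the hashtags in the cluster led by Il10 and at 341.5 to 408 CPM in the cluster led by Il1r2. Tnfrsf4 was higher in Th2-like cells, at 674 to 957 CPM over the 4 hashtags, than in Th1-like cells, at 213.5 to 266.5 CPM, a log2 fold of 1.88 (SE 0.09), and in Th17-like cells, at 189 to 464 CPM. In the CD69-positive cells of day 29 the cluster led by Il1r2, at 408 CPM (377.5 to 439.9), did not lie above the Th17-like cells, at 464 CPM (375 to 567). Tnfrsf8 was higher in Th2-like cells, at 14.6 to 33.7 CPM over the hashtags, than in Th1-like cells, at 0 to 3.46 CPM, and Th17-like cells, at 0 to 3.69 CPM, with log2 folds of 3.59 (SE 0.38) and 4.97 (SE 0.56). These rest on 7 UMIs in Th1-like and 2 in Th17-like cells. The Th17-like class did not include a cluster of 126 cells led by Il17a, which kept no class name. With clusters at resolution 0.4, where Il17a led the Th17-like class, the fold over Th17-like cells was 1.65 and that over Th1-like cells 3.70. Tnfsf8 was higher in Th2-like cells by log2 folds of 1.74 and 0.94, and Icosl by 1.41 and 1.49. Icosl had 28 UMIs in Th17-like cells, 19 of them in the CD69-negative cells of day 29, and its fold over them was 0.88 without the CD69-negative hashtag of day 46 and 1.90 without that of day 29. Icos went the other way, at 348 to 422 CPM in Th2-like, 432 to 612 CPM in Th1-like and 664 to 1016 CPM in Th17-like cells.

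In edgeR's quasi-likelihood test with the hashtag as a block and Benjamini-Hochberg adjustment over the 10 tests of this family, Tnfrsf4 had a log2 fold of 1.88 over Th1-like cells with adjusted p = 5.4e-13 and of 1.67 over Th17-like cells with adjusted p = 3.1e-09, higher in 4 of 4 hashtags. In the same edgeR test Icos had -0.33 against Th1-like cells with Benjamini-Hochberg adjusted p = 0.0012 and -1.09 against Th17-like cells with adjusted p = 1.2e-10, lower in 4 of 4 hashtags. Of the other 6 edgeR quasi-likelihood tests, each with the direction held in 4 of 4 hashtags, the Benjamini-Hochberg adjusted p ranged from 1.8e-11 for Tnfsf8 over Th1-like cells (log2 fold 1.74) to 5.5e-04 for Icosl over Th17-like cells (log2 fold 1.49). Tnfsf4 had 10 UMIs in Th2-like cells and was removed by the count filter. The p-values set the class difference against its spread over these 4 hashtags, which are 4 conditions of 1 run. Whether both populations of a day came from the same mice is not told by the sources used here. Shares of cells with a Y-linked UMI were alike within a day (13.7% and 14.6%, then 0.312% and 0.531%). The hashtags may therefore not be independent samples. The edgeR method also draws on the spread of the other genes in the fit, so p-values this small do not rest on 4 hashtags alone. The Icos difference from Th1-like cells turned to 0.43 after cells were filtered more strictly and clustered anew. There the Th2-like class was 1 cluster of 501 cells led by Il10 and Il4, in place of clusters of 1012 and 743 cells. A cluster of 1148 cells kept no class name there. The limit of 5% mitochondrial UMIs removed no listed cell, so cells were lost only to the limit of 1000 UMIs. The turn went with a change of class membership. At resolution 1.2 the Th2-like class was also a single cluster, of 498 cells, but Icos had -0.61 against Th1-like cells. A smaller class alone thus did not bring the turn. The stricter filter brought Icos to -0.33 against Th17-like cells, with Tnfrsf4 at 3.05 and 2.55 and Tnfsf8 at 3.09 and 1.88 over Th1-like and Th17-like cells. Against naive or central memory cells, tested only there, Tnfrsf4 had 2.42, Tnfsf8 2.25 and Tnfrsf8 6.13. Icos had 0.02, with adjusted p = 0.85 in edgeR's quasi-likelihood test (Benjamini-Hochberg over 12 tests). The main clustering, untested for this class, gave other values. There Icos was lower in Th2-like cells in 4 of 4 hashtags, at 348 to 422 against 481 to 783 CPM. Tnfrsf4 was higher there by log2 ratios of 0.71 to 1.44 (10 CPM added). The CD69-positive hashtags held only 17 and 16 naive or central memory cells there.

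**Figure D3:**
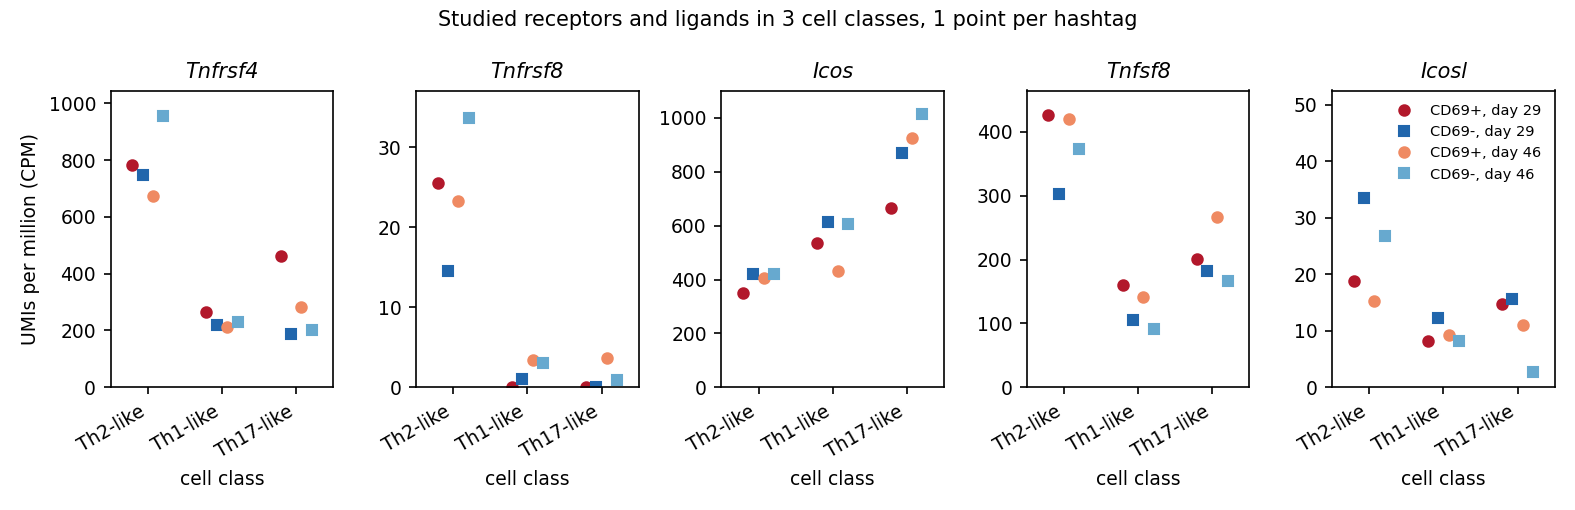
Each point is the CPM of a gene in 1 class of 1 hashtag, for Th2-like, Th1-like and Th17-like cells, with circles for CD69-positive and squares for CD69-negative cells of day 29 and day 46. Tnfrsf4 lies at 674 to 957 CPM in Th2-like cells, at 213.5 to 266.5 CPM in Th1-like cells and at 189 to 464 CPM in Th17-like cells, and Icos lies lowest in Th2-like cells, at 348 to 422 CPM.

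Within classes, CD69-positive and CD69-negative cells still differed in egress genes. Klf2 had log2 folds on day 29 and day 46 of -1.71 and -1.41 in Th2-like, -1.91 and -2.54 in Th1-like, -1.95 and -1.71 in Th17-like and -3.58 and -3.65 in cycling cells. S1pr1 had -1.06 and -0.88, -1.27 and -2.21, and -2.34 and -1.51 in the first 3 of these classes. Inside the Th2-like class Il13 had 1.28 and 0.51 and Il5 had 1.49 and 0.08, while the whole Th2 list of 16 genes had medians of -0.07 and 0.26. Of the studied receptors, Tnfrsf4 had 0.06 and -0.50 inside this class and Tnfrsf8 had 0.53 and -0.39 (351 UMIs in all), so that neither was higher in CD69-positive Th2-like cells on day 46. The day 29 values mix the clusters of this class. On that day 339 of 517 CD69-positive but 64 of 182 CD69-negative cells came from the cluster led by Il10, where Tnfrsf4 was higher. As most CD69-negative Th2-like cells of day 29 came from the cluster led by Il1r2, Il13 was also read by cluster on that day. It was at 4466 CPM in CD69-positive and 2633 CPM in CD69-negative cells of the cluster led by Il10 (cluster 0), and at 2923 and 719 CPM in the cluster led by Il1r2 (cluster 2). The inhibitory receptor gene Lag3 was higher in CD69-positive Th1-like cells (0.65 and 1.46, 160 UMIs in all), as was Fgl2 with 1.11 and 1.37, and in Th17-like cells with 1.14 and 1.67 (311 UMIs in all). The integrin gene Itgb1 was lower, with -0.96 and -1.20 in Th1-like and -1.06 and -1.43 in Th17-like cells. The numbers of genes at least 2-fold higher and lower on both days were 1 and 3 in Th2-like, 4 and 10 in Th1-like, 6 and 10 in Th17-like and 15 and 11 in cycling cells. Clusters are drawn from expression, which makes differences within a class smaller by construction, the cycling class had 22 and 20 CD69-negative cells, and the Th17-like class had 34 and 60 CD69-positive cells.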

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

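Among the tests described here, those of single barcodes, of swapped hashtags, of depth and of which genes stayed without cycling cells were chosen only after the result was seen. Thinned cells were a setting fixed in advance, while the settings without cycling cells and with Xist cells were added after the data had been seen, with the bounds of the test written before they were run. Some genes lay in opposite directions in 2 comparisons of the same kind, differences that were not tested. Il9, a cytokine of mast cell and T cell growth, had log2 folds of CD69-positive over CD69-negative cells of 1.585 on day 29 and -2.137 on day 46, and of day 46 over day 29 of -1.658 in CD69-positive and 2.064 in CD69-negative cells. A single barcode held 202 of its 226 UMIs in the CD69-positive cells of day 29, and another held 238 of 246 in the CD69-negative cells of day 46. The chemokine Ccl4 had -1.002 on day 29 and 0.9496 on day 46 between CD69 populations, with 46.3% and 49.3% of its day 29 UMIs in 1 barcode of the CD69-positive and CD69-negative cells. Between days, the eosinophil growth factor Il5 had -0.7213 in CD69-positive and 0.8194 in CD69-negative cells, with at most 13.1% of its UMIs in 1 barcode of any population. Phlda1 had -0.7779 and 0.6037, with at most 3.39% in 1 barcode. The chemokine Ccl1 had 0.7275 and -2.218, with 44.4% of the UMIs of CD69-negative cells of day 29 in 1 barcode.

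Cd69 mRNA was near equal in cells sorted as CD69-positive and CD69-negative, with log2 folds of -0.15 and 0.20. Swapped or blended hashtags were argued against by S1pr1 and Klf2, whose log2 ratios, upper counting bounds included, reached no higher than -3.455 on both days. Induction of early genes during handling of the tissue, alike in both populations, could raise Cd69 mRNA in CD69-negative cells. CD69-negative cells rich in dissociation and immediate early genes held a Cd69 UMI more often than cells poor in them, 54.2% against 40.5% on day 29, a ratio of 1.338, and 54.2% against 39.9% on day 46, a ratio of 1.359, after thinning. The ratio lay between the bounds of 1.2 and 1.5 set beforehand, so handling cannot be told apart from CD69 protein set after transcription, and the latter was not tested.

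Differences by CD69 were alike on both days, with r = 0.870 across genes, which are not independent replicates. More cycling cells in the CD69-positive populations were argued against as the whole cause, since without the cycling cluster 26 genes were higher and 44 lower on both days against 37 and 44, a ratio of 0.7027 for the higher genes, and 41 of the 44 lower genes stayed, a share of 0.9318. Of the 37 higher genes 21 stayed, a share of 0.5676 (exact 95% interval 0.395 to 0.729), so for them cycling cells stay open as a cause. For more UMIs per cell, CPM already divides out the total, so thinning could test only the greater weight of cells with more UMIs. Thinning every cell to 2000 UMIs kept 30 of the 37 and 37 of the 44, the lower share being 0.8108 (0.648 to 0.920). That argues against such weight as the whole cause, but does not address why CD69-positive cells held more UMIs. Residence in tissue is named by the design and stays open as the source of this pattern, untested. The populations were sorted on CD69, and both days lie within a challenge or on the day after one. Residence can thus not be told apart from a response to the challenge, and each condition had 1 hashtag. The mix of cell classes stays open too and was not tested. The naive or central memory cluster held 472 and 356 CD69-negative but 17 and 16 CD69-positive cells on day 29 and day 46. Th2-like cells numbered 517 and 836 among CD69-positive and 182 and 220 among CD69-negative cells. Within classes, which hold fewer cells, r between days was 0.25 (Th17-like) to 0.41 (Th1-like).

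Genes at least 2-fold apart between days, 12 gene and population pairs outside the left-out classes, were set against the sex of the cells. Cells with a Y-linked UMI made up 13.7% and 14.6% of CD69-positive and CD69-negative cells on day 29 and 0.312% and 0.531% on day 46. With only cells that held Xist and no Y-linked UMI, the median ratio of the new to the old fold was 1.025 (quartiles 0.757 to 1.149), which argues against male cells as the cause. Single barcodes held over 50% of the UMIs for 2 of the 12, Retnla and Sftpc, which argues against them for the pattern but not for those genes. The day and the challenge it follows stay open, as do the mice pooled on each day.

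In the class tests each hashtag gave both classes, so the sums can be regrouped only by swapping classes within hashtags. That makes 8 splits, too few for a share under 0.05. The splits set beforehand ignore the hashtags, so their result, 1 of 35 for both comparisons, is not used as evidence. With the hashtag as a block, 1 of 8, the real one, gave a mean F as large for Th2-like against Th1-like cells, with 173.7 against a highest other value of 3.37, and 1 of 8 for Th2-like against Th17-like cells, with 87.9 against 3.64. Every other swap sets the class difference of some hashtags against that of others, which lowers its mean F by construction. The gap is thus not used as evidence either.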

How the results depend on the processing

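The 2-term fit and the settings on cycling cells, Xist, the Sftpc-rich barcode, the filter on either day, clustering and 50 cells per class were chosen only after the data had been seen. The 37 genes higher and 44 lower in CD69-positive cells on both days ranged from 26 to 52 and from 44 to 62 over all settings but 1: with 50 CPM added they were 13 and 23, as a larger added value shrinks folds of low genes. Thinning kept 30 of the 37 and 37 of the 44, the CD4 setting 30 and 42, and leaving out the cycling cluster 21 and 41. The day counts are small. In CD69-negative cells, genes higher on day 46 went from 1 to 2 with 1 CPM added, with the stricter hashtag margin, with CD4 cells and with Xist cells, and to 3 after thinning. Genes lower went from 4 to 7 with 1 CPM added, the stricter margin and Xist cells, and to 2 without the Sftpc-rich barcode. In CD69-positive cells, genes higher went from 7 to 4 with 50 CPM added and to 12 with the stricter margin, and genes lower from 2 to 1, to 24 and, after thinning, to 5. The stricter margin left 127 of 1078 CD69-positive cells of day 29. The cause was not tested.

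A fit of the 4 sums with CD69 and day as terms, which left 1 residual degree of freedom and took the other day as the replicate, called 1496 genes higher and 1352 lower by CD69 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, among 11232 genes. DESeq2 called 585 and 479. For the day, edgeR called 6 higher and 13 lower, with 587 genes at an unadjusted p under 0.05, and DESeq2 called 4 and 8, with 134. The cause of the gap was not tested.

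Of 127 gene folds of at least 2-fold, 9 turned round under some setting. Retnla on day 29 went to 0.0566, 0.00996 and 0.14 with CD4 cells, Xist cells and without the Sftpc-rich barcode, and Sftpc to 0.0804, 0.0236 and 0.0262. Between days in CD69-negative cells Retnla went to 0.15 without the barcode, and Sftpc to 0.33, 0.10 and 0.17 in the same 3 settings. Il2 went to -1.21 by CD69 on day 29 and to 0.81 by day in CD69-positive cells with the stricter margin. Without the cycling cluster Hist1h2ae went to -0.0335 and -0.0855 on day 29 and day 46 and Hist1h1b to -0.39 on day 46. Over all settings 829 gene folds stayed within their counting interval, 426 left it without turning and 15 turned. The setting with a higher minimum of UMIs per gene changed neither the counts nor the added CPM. Its gene folds equal the main ones by construction. They are among those that stayed and say nothing about robustness. List medians stayed in 755 cases and moved in 81, and shares stayed in 69 and moved in 39. A list median stayed if its shift lay within the typical counting interval of its members, except with all listed members, where a fixed limit was used. A turn was counted only for medians of at least 2-fold, so smaller medians that changed sign count as stayed or moved. Thinning took the chemokine median by CD69 on day 29 from -0.77 to -0.35, and all listed members in place of measured ones took the lipid medians from 0.61 and 0.50 to 0.25 and 0.03.

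Of the class tests, 104 kept direction and side of the threshold and 1 turned: Icos in Th2-like over Th1-like cells was 0.43 with the stricter cell filter (adjusted p = 0.0039 in edgeR's quasi-likelihood test, Benjamini-Hochberg over 12 tests), against -0.61 to -0.26 over the other settings that formed classes anew. Its Benjamini-Hochberg adjusted p over the remaining alternatives, from edgeR's quasi-likelihood test and DESeq2, ranged from 1.6e-04 to 0.0101. With the stricter cell filter the Th2-like class was 1 cluster led by Il10 and Il4 with 40 to 206 cells per hashtag, against 182 to 836 in the main clustering. The turn thus went with a change of class membership, and its cause was not tested further. Leaving out each hashtag in turn gave -0.44 to -0.28, DESeq2 -0.32 and the fit with no replicate block -0.35. Tnfrsf4 ranged from 1.74 to 3.05 over Th1-like and from 1.43 to 2.55 over Th17-like cells, Tnfsf8 from 1.60 to 3.09 and from 0.82 to 1.88, Icos over Th17-like cells from -1.40 to -0.33 (the latter with the stricter cell filter), Tnfrsf8 over Th17-like cells from 1.65 (resolution 0.4) to 5.73, and Icosl over Th17-like cells from 0.88 to 1.90. At resolution 1.2 the count filter removed Tnfrsf8 in both comparisons and Icosl over Th17-like cells. With the stricter cell filter it removed Icosl in both. These cases are in neither the tally nor the ranges. The tests with 50 or more cells repeat others: the main ones over Th1-like cells, and those without the CD69-positive hashtag of day 29 over Th17-like cells. The authors' natural log values gave the same direction in all 10.

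Tests of 1 condition against another were not run, since each has 1 hashtag, and so neither were their alternatives (no filter, left-out hashtags, a fit of 2 conditions alone, set tests) nor class shares. Hashtags carry no replicate numbers, and CD69-positive and CD69-negative hashtags were paired by day only in the fit with CD69 and day as terms. Depth limits Tnfsf4, with 27 UMIs in all, and Tnfrsf8 outside Th2-like cells.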

Other observations

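A cluster of 419 cells led by Il21, Lta, Prelid2, Il4 and Rgs16, to which no class name was given, carried more Tnfrsf4 than any other cluster of 20 or more cells in each of the 4 hashtags. Tnfrsf4 was at 1436 and 1385 CPM in its CD69-positive and CD69-negative cells of day 29 and at 1230 and 1746 CPM on day 46, and 74.3% to 81.8% of its thinned cells held a Tnfrsf4 UMI. Tnfsf8, the ligand of CD30, was at 834, 901.5, 783 and 892 CPM in the same order. Il21 is the cytokine by which helper T cells act on B cells, and Lta encodes lymphotoxin. The cluster was found by looking at the data, and its levels were not tested.

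A cluster of 126 cells was led by Il17a, Ppp1r14c, Tcrg-C1, Tff1 and Ckb. Tcrg-C1 is a constant gene of the gamma chain of the T cell receptor. Il17a was at 7734 CPM (7404 to 8075) in its CD69-positive cells of day 29 and at 6191 CPM on day 46, with Tcrg-C1 at 209.7 and 254.8 CPM. It held 37 and 71 CD69-positive cells, and 16 and 2 CD69-negative cells, on day 29 and day 46. Markers of gamma-delta T cells summed to 40.3 and 39.5 CPM in all CD69-positive and CD69-negative cells of day 29 and to 63.9 and 44.3 CPM on day 46.

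No test of the values in this part was run, before or after they were seen. Among UMIs of T cell receptor beta variable genes, Trbv3 made up 19.4% and 15.02% in CD69-positive and CD69-negative cells of day 29 and 14.5% and 8.26% on day 46. Trbv15 made up 4.27%, 3.47%, 10.9% and 6.62% in the same order, and Trbv1 9.62%, 13.9%, 9.46% and 12.9%. The totals behind these shares were 14426, 10761, 16186 and 9586 UMIs. A UMI can come from a few expanded clones, which were not analysed here.

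Markers of other cell types were summed in the order of CD69-positive and CD69-negative cells of day 29 and then of day 46. T cell markers summed to 5745, 5876, 5870 and 5278 CPM and CD4 markers to 608, 616, 612 and 545 CPM. CD8 markers, in which Ccl5 was the most abundant, summed to 675, 1726, 675 and 1423 CPM. Markers of innate lymphoid cells type 2, among which Il7r was the most abundant, summed to 1595, 1866, 2208 and 2172 CPM, and those of natural killer T or MAIT cells to 197.5, 318, 152 and 286 CPM. B cell markers, nearly all Ighm, summed to 24.3, 64.9, 20.6 and 42.9 CPM and plasma cell markers, mostly Xbp1, to 163, 128, 155 and 167 CPM. Monocyte markers, with Ly6c2 among them and Nr4a1 the most abundant, summed to 540.2, 813, 518 and 764 CPM. Alveolar macrophage markers summed to 258, 271, 291 and 262 CPM, nearly all of it Ctsd, dendritic cell markers to 219, 262, 211 and 212 CPM, most of it Bst2, and fibroblast markers to 48.4, 19.3, 50.8 and 22.7 CPM, nearly all of it Gsn. Sums carried by 1 gene say little about the presence of these cells. Epithelial markers summed to 27.4, 146.5, 28.9 and 35.7 CPM, the second value including the barcode rich in Sftpc, and endothelial markers, nearly all Pecam1, to 24.4, 31.6, 17.5 and 28.4 CPM. Markers of interstitial macrophages, neutrophils, eosinophils, basophils or mast cells, red blood cells and platelets each summed to at most 7.35 CPM.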
